A study of Homo sapiens with 77 samples.

How the data were processed

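Binding of WDR5 was measured by ChIP-seq, steady-state RNA by RNA-seq and engaged RNA polymerase by PRO-seq in cultured human leukaemia cell lines, 77 samples in 25 groups by treatment, line, assay and antibody. MV4:11 cells carry an MLL-AF4 fusion, and K562 cells carry BCR-ABL1. C6 and C3 are code names of compounds directed at the WIN site of WDR5, and C6nc is the inactive control compound for C6. Nutlin-3, called Nutlin here, is an inhibitor of MDM2. Per the labels, ChIP-seq cells received 2 uM C6, 2 uM C6nc or 0.1% DMSO for 4 h, and RNA-seq cells received 2 uM C6, C6nc or Nutlin or 0.1% DMSO for 72 h. MV4:11 cells for PRO-seq received C3 for 15, 30 or 60 min or DMSO (0 min), with no dose in the sample labels.

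The RNA-seq values deposited by the authors were raw read counts per gene, in a table of 55300 genes and 30 libraries for both lines and in a table of 55169 genes and 6 libraries for the Nutlin set. The PRO-seq table deposited by the authors held raw counts for 20582 genes and 8 libraries, separately for a promoter-proximal window and for the gene body, per the file headers. It also held a gene-body density deposited as signal, reads per base not scaled for library size, which is the same count divided by length and was not analysed here. For ChIP-seq the authors deposited 1 list of peaks per sample in the layout of MACS2, in which the enrichment is a ratio, fold enrichment over the local background of the caller, and the strength of each peak is the −log10 of its q-value. The submitters' processing notes name STAR, featureCounts, DESeq2, Bowtie2, MACS2, DiffBind and cutadapt and the genome build hg19. Versions, roles, the control track of the peak calling and its thresholds were not given in the sources used here, and no peak had a −log10 q far below 2, which the values themselves show. The build of the Nutlin table was not stated, and its genes were joined to the other table by gene identifier, which matched 49406 genes. Positions are on hg19, counted from 1, and come from the deposited tables, so exons, introns and untranslated regions could not be assigned.

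The columns of the Nutlin table carry replicate numbers 2, 3 and 5 that the sample labels do not tie to single samples, so its libraries are named by column number and enter only as members of their group. The other samples were grouped by their labels alone. Replicate numbers were tested as pairs by correlating, across genes, each library's departure from its group mean. The lowest correlation between libraries with the same number was 0.027 in MV4:11 and −0.087 in K562 RNA-seq and −0.60 in PRO-seq gene bodies, so the samples were taken as unpaired. No label says whether replicates were separate cultures, so every p-value measures only the spread between these samples. IgG libraries, the density columns and all IgG peak lists were left out because the comparisons concern WDR5 peaks and raw counts.

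Differential counts were tested in R 4.3.3 with edgeR 4.0.16 (quasi-likelihood F test, two-sided, TMM factors, its default filter on low counts), with 1 fit for the 15 libraries of each line, 1 for the Nutlin set and 1 per PRO-seq region. A gene was called at a Benjamini-Hochberg adjusted p below 0.05. The effect of C6 in MV4:11 minus that in K562 was tested as an interaction in a fit of the 30 libraries, and the effect of C6 minus that of Nutlin in a joined fit of 21 libraries, each treatment against its own DMSO libraries. The ratio of promoter-proximal to gene-body counts was tested as a region by time interaction with a term for each library. Log2 CPM values used a prior count of 2. Errors of log2 fold changes are standard errors from the fit, and other errors are SD.

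Gene lists were fixed before the data were examined, as were the tests, the thresholds, most alternatives and the rule for naming genes: cytosolic ribosomal proteins (79 genes), mitochondrial ribosomal proteins (75), translation factors (37), noncoding snoRNA host genes (13), ribosome biogenesis (35), p53 targets (40), cell cycle (45), MLL-fusion targets (20), myeloid markers (33), erythroid and megakaryocyte markers (28), lymphoid and stromal markers (18), WDR5 partner complexes (26), the BCL2 family (15), the ATF4 response (24), interferon-stimulated genes (28), histones (21), cholesterol synthesis (22), oxidative phosphorylation (31) and housekeeping controls (12). Each list and the set of WDR5-bound genes was tested with camera of limma 3.58.1, which compares a set with all other genes, at a preset correlation between genes of 0.01 and then with a correlation estimated from the libraries. The p-values were adjusted over the 20 sets of a contrast. The number of called members is given over all genes tested and adjusted over the list alone.

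WDR5 peaks with the antibody D9E1I were merged with bedtools 2.31.1 into consensus regions present in at least 2 DMSO replicates, and a region counted as found in a library when a peak overlapped it by 1 bp or more. A gene was called WDR5-bound when a consensus region lay within 1 kb of its transcription start site. For each RNA-seq library the mean log2 CPM of unbound ribosomal protein genes was subtracted from that of bound ones, and groups were compared by exact two-sided permutation tests, with 95% intervals holding the shifts that the exact test does not reject. Shares of regions carry 95% Wilson intervals, which like all counting errors here cover counting error only, since reads were not marked by molecular identifiers. Python 3.11.15, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for these steps.

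Genes named in the text follow a rule. For C6 and Nutlin against DMSO it takes the 6 largest rises and 6 largest falls among called genes with a mean log2 CPM of at least 3 and no overlap between groups, up to 3 members with the smallest p from each list with at least 3 called, and always WDR5, CDKN1A, MDM2, MYC, HOXA9 and MEIS1. Some genes the rule takes are not reported here. It takes the 5 called genes with the smallest p for C6nc and, in each direction, for differences between effects, the 8 with the smallest p per direction for each PRO-seq time and region, and the 10 best-ranked DMSO regions per line for ChIP-seq. Genes outside the rule are said to be chosen after their values were seen. The rule was also applied to the fit of replicates 1 to 3 in MV4:11 and of replicates 4 and 5 in K562, which were added after seeing the data.

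RNA-seq libraries held 15.4 M to 49 M counts (M, mega), those of the Nutlin set 36.8 M to 48.7 M, and PRO-seq libraries 12.2 M to 25.5 M in gene bodies and 1.23 M to 2.67 M in promoter-proximal windows. Peak lists hold no depth, so the depth of the ChIP-seq libraries is unknown. In data simulated from these libraries, 61 of 100 genes changed 2-fold and 13 of 100 changed 1.5-fold were called with the MV4:11 design, and 73 and 26 with K562. The numbers were 94 and 70 for the Nutlin set, 82 and 45 for PRO-seq gene bodies at 15 min, 53 and 6 for promoter-proximal windows and 31 and 3 for the difference between lines. Real libraries may allow fewer. A search for duplicated libraries found none, the smallest chi-square per degree of freedom between libraries of the same group being 7.12 in RNA-seq and 1.68 in PRO-seq gene bodies.

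Alternatives tried were DESeq2 1.42.0 (Wald test), RLE size factors, library size alone, no filter on low counts, a 2-fold threshold in addition, a fit of only the groups compared, a replicate block, and leaving out each library in turn. For peaks they were a −log10 q of at least 5, an overlap of 50% of the shorter peak, consensus in every replicate, and a distance of 5 kb. Added after seeing the data were fits of replicates 1 to 3, of replicates 4 and 5, a term for this batch, and fits without the MV4:11 libraries labelled C6nc replicate 4 and C6 replicate 5.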

Results

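WDR5 is a WD40-repeat protein of several chromatin complexes, and its WIN site is a pocket that binds short peptide motifs of partner proteins. The data cover where WDR5 sits on chromatin, which genes RNA polymerase transcribes within an hour of a WIN-site compound, and which RNAs differ after 72 h of treatment. ChIP-seq with the antibody D9E1I had 3 MV4:11 replicates and 2 K562 replicates each of DMSO, C6nc and C6, and a second WDR5 antibody, 429A, had 3 MV4:11 replicates under DMSO. RNA-seq had 5 replicates each of DMSO, C6nc and C6 in both lines, and a separate set of 3 Nutlin and 3 DMSO libraries in MV4:11. PRO-seq, which maps engaged RNA polymerase by run-on, had 2 replicates of MV4:11 at each of 0, 15, 30 and 60 min of C3.

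The RNA-seq libraries fell into 2 sets, called batches here, that no label names, and whether they differ in handling or in the cells is not known. Replicates 1 to 3 held 15.4 M to 26.2 M counts in MV4:11 and 16.3 M to 29.3 M in K562, and replicates 4 and 5 held 39.1 M to 47.2 M and 37.6 M to 49 M. Despite the lower depth, between 30275 and 49488 genes had a count in replicates 1 to 3 of MV4:11, against 29336 to 29864 in replicates 4 and 5. The first principal component held 70.6% of the variance in MV4:11 and 77% in K562 and separated replicates 4 and 5 from the others. In MV4:11 under DMSO, CDKN1A was at 6.08 to 6.24 log2 CPM in replicates 1 to 3 and 8.0 and 8.1 in replicates 4 and 5, and SLFN11 at 4.17 to 4.34 and 0.73 and 1.10. The mitochondrial 16S ribosomal RNA gene MT-RNR2 took 29.1% ± 8.50 (SD, n = 5) of counts in the MV4:11 libraries labelled C6, 25.3% ± 2.61 in those labelled C6nc and 22.6% ± 4.87 under DMSO. In replicates 1 to 3 these shares were 33.8% ± 6.86, 26.1% ± 1.62 and 26.1% ± 1.14 (n = 3). In K562 they were 15.6% ± 2.00, 15.9% ± 2.42 and 17.0% ± 4.25 (n = 5).

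In MV4:11 cells under DMSO, WDR5 occupied a larger share of ribosomal protein gene promoters than of the promoters of any other fixed list. Of 159 consensus regions, 113 were in every replicate and 136 (85.5%) lay within 1 kb of a transcription start site. Cytosolic ribosomal protein genes were bound at 39 of 75 (52%), against 0.781% of all genes. Translation factor genes were bound at 7 of 35 and noncoding snoRNA host genes at 2 of 9, whereas mitochondrial ribosomal protein genes were bound at 1 of 72 and p53 targets, cell cycle genes and MLL-fusion targets at 0. The highest-ranked regions included those at RPS3 (11:75110473-75111068), with a fold enrichment of 48.1 ± 25.8 given by the authors' caller (SD, n = 3), RNPS1 (16:2317562-2318316; 49.8 ± 29.8), RPL26 (17:8285891-8286821; 55.5 ± 36.9), RPL35 (9:127623604-127624613; 48.1 ± 39.2) and NACA (12:57118539-57119401; 40.7 ± 22.8). RNPS1 encodes a splicing factor and NACA a chaperone of nascent chains.

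K562 cells had more regions, 525, of which 420 (80%) were at a start site, and ribosomal protein genes were again the list bound most often. WDR5 lay at 44 of 75 (58.7%), against 2.43% of all genes. The 39 ribosomal protein genes bound in MV4:11 were all bound in K562, and 143 genes in total were bound in both lines. The highest-ranked K562 regions included those at CCT4 (2:62115010-62115978; 70.6 ± 9.31), which encodes a subunit of a cytosolic chaperonin, and NACA (12:57118385-57119573; 69.1 ± 5.63). The snoRNA host gene SNHG15 (7:45025638-45026578; 68.9 ± 9.73) also ranked high. Of the 159 MV4:11 regions, 133 (83.6%, Wilson 95% interval 77.1 to 88.6) overlapped a K562 region, and 131 of the 525 K562 regions (25.0%) overlapped one of MV4:11. With the second antibody, 100 of the 159 regions (62.9%, 55.2 to 70.0) were found.

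After 4 h of C6, most WDR5 regions were no longer called in MV4:11 cells. A peak was found at 25.4% ± 18.0 of the 159 regions after C6 and at 75.3% ± 16.7 after C6nc (SD, n = 3), a difference of −49.9 percentage points (exact two-sided permutation p = 0.1, the smallest 3 against 3 allows). Of the 41 regions at ribosomal protein genes, 39, 11 and 14 had a peak in the C6 replicates and 41, 41 and 39 in the C6nc replicates. Of the other 118 regions the numbers were 34, 9 and 14 after C6 and 94, 94 and 50 after C6nc. Peaks per library numbered 248 ± 43.7 under DMSO, 185 ± 81.5 after C6nc and 49.3 ± 33.0 after C6, a difference from DMSO of −199 for C6 (exact permutation p = 0.1) and −63.3 for C6nc (exact permutation p = 0.3). Leaving out 1 replicate number from every group, which also changed the consensus to between 127 and 129 regions, gave 18.9% to 39.1% of regions found after C6.

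In K562 cells, C6 and C6nc left similar shares of the 525 regions with a peak, 72.8% ± 5.93 and 76.2% ± 18.9 (SD, n = 2), with a difference of −3.43 percentage points. The exact permutation p was 1, the smallest that 2 against 2 allows is 0.333, and no 95% interval of the difference can be formed from so few libraries, so the compounds are not shown to act alike here. All 44 regions at ribosomal protein genes had a peak in 1 C6 replicate and 43 in the other. Peaks per library numbered 1092 ± 450 under DMSO and 732 ± 266 after C6 (exact permutation p = 0.667). Whether the loss of peaks differed between the lines was not tested. Peak lists give no occupancy level, and the depth behind them is unknown.

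**Figure D1:**
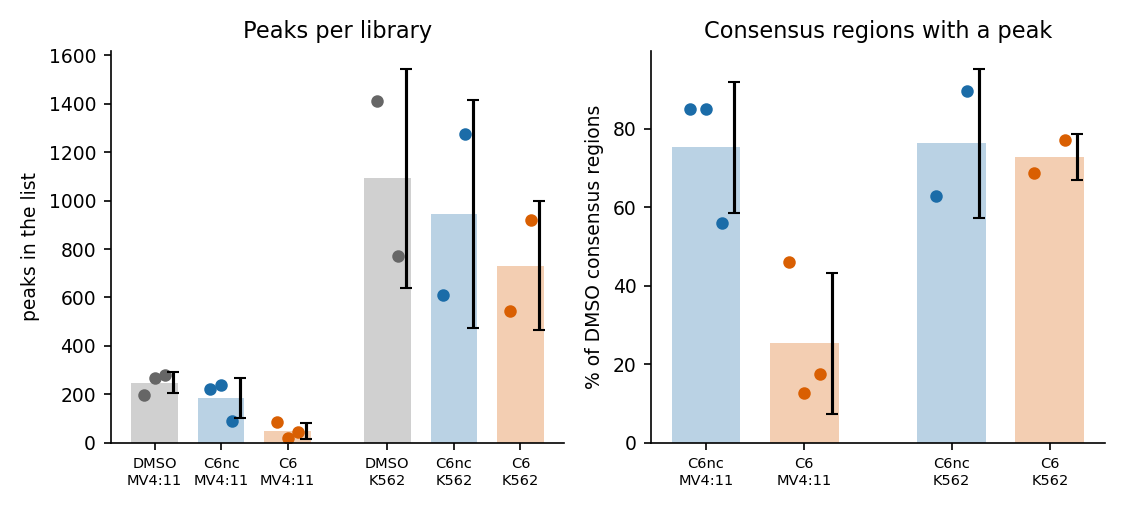
Left, number of WDR5 peaks per ChIP-seq library (antibody D9E1I) under DMSO, C6nc and C6 in MV4:11 (n = 3) and K562 (n = 2), with bars for means, error bars for SD and points for single libraries. Right, percentage of the DMSO consensus regions of each line with a peak after C6nc and C6, which was lowest for C6 in MV4:11 (25.4% ± 18.0) and between 72.8% and 76.2% on average in the other 3 groups.

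PRO-seq asked which genes lose or gain engaged polymerase within an hour of C3. Gene bodies of ribosomal protein genes and a few other WDR5-bound genes fell from 15 min on, and 3 genes rose. Both counts rest on 2 libraries at 0 min, and without replicate 1 of these most calls were rises (358 of 423 at 15 min, 931 of 995 at 30 min and 1008 of 1081 at 60 min). Such a fit assumes that the lone 0 min library varies like the other groups, so it shows how far the counts depend on that library and not that genes rose. EEF1G (11:62327073-62341460), a subunit of the elongation factor that delivers tRNA, fell from 6.90 ± 0.08 to 5.91 ± 0.06 log2 CPM (SD, n = 2) by 15 min. Its log2 fold change was −1.0 ± 0.09 (SE; edgeR adjusted p = 0.00104), and it stood at −1.24 ± 0.09 at 30 min and −1.22 ± 0.09 at 60 min. CSNK1E (22:38686697-38714089), casein kinase 1 epsilon, fell at 15 min (−0.85 ± 0.11, adjusted p = 0.00275), 30 min (−1.14 ± 0.11, adjusted p = 0.000577) and 60 min (−1.29 ± 0.11, adjusted p = 0.000135). CCT7 (2:73461364-73480150) and CCT4, chaperonin subunits, changed by −0.94 ± 0.10 and −0.88 ± 0.10 at 30 min (adjusted p = 0.002 and 0.00282).

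Gene-body calls numbered 52 at 15 min (3 up, 49 down), 31 at 30 min (all down) and 52 at 60 min (all down) of 17998 genes tested with edgeR. The largest group was the ribosomal proteins, of which 33, 20 and 29 of 74 fell at the 3 times (49, 38 and 41 fell, and at 60 min 3 rose, when adjusted over the list alone). Their median log2 fold changes were −0.64, −0.49 and −0.53, and the camera test gave an adjusted p of 7.01e-196 at 15 min. With an estimated correlation the adjusted p = 0.0327, 0.248 and 0.0675 at the 3 times, so the call held at 15 min. At 15 min RPL35A (−1.18 ± 0.12), RPS7 (−1.11 ± 0.12), RPS14 (−1.04 ± 0.10) and RPL26 (−1.04 ± 0.12) fell. At 60 min the largest falls by p included RPL35A (−1.20 ± 0.12), RPL34 (−1.16 ± 0.12), RPS24 (−0.96 ± 0.08) and the coiled-coil protein gene PRRC2B (9:134305477-134375575; −0.85 ± 0.09). The 3 rises at 15 min were FLRT1 (11:63871362-63886645; 1.36 ± 0.23, adjusted p = 0.0214), a membrane protein, the adaptor GRB10 (0.47 ± 0.08, adjusted p = 0.0339) and CDKN1A (6:36644237-36655116; 0.63 ± 0.11, adjusted p = 0.0339). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at 7.82 ± 0.03 against 7.17 ± 0.28 log2 CPM.

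Among ribosomal protein genes the falls were concentrated at those with a WDR5 region. The 38 bound ones had median log2 fold changes of −0.93, −0.73 and −0.79, with 30, 18 and 26 called, and the 36 others −0.23, 0.10 and 0.10, with 3, 2 and 3 called. Of 49, 31 and 52 gene bodies that fell, 44, 27 and 43 were bound (Fisher's exact two-sided p at most 7.27e-53, over genes not independent). The 157 bound genes had medians of −0.15, −0.12 and −0.17 (camera adjusted p = 8.64e-110 at 15 min), and with an estimated correlation the adjusted p = 0.0428, 0.248 and 0.0675. Noncoding snoRNA host genes had a median of −0.45 at 15 min with 2 of 9 called (camera adjusted p = 2.21e-16, and adjusted p = 0.0371 with an estimated correlation). Translation factors (median −0.06, 2 down, camera adjusted p = 2.47e-13) gave an adjusted p = 0.288 with an estimated correlation. Targets of p53 had a median of 0.12 at 15 min, 1 called up and 4 up when adjusted over the list alone (camera adjusted p = 3.22e-08, and adjusted p = 0.125 with an estimated correlation).

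Of the gene bodies that fell, 28 did so at all 3 times, 25 of them WDR5-bound and 20 of them ribosomal protein genes, and 59 did so at any time. The 3 times share their 0 min libraries. The overlaps of falls were 28 genes (15 and 30 min), 43 (15 and 60 min) and 30 (30 and 60 min), against 0.0844, 0.142 and 0.0896 for independent lists. The 2 controls cannot be split and may give part of the excess. In 20 simulations of unchanged groups sharing them 0 falls overlapped, arguing against sharing as the whole cause. Sharing is enough for r over all genes (0.387, 0.523 and 0.552, simulated 0.541, 0.541 and 0.533). Without the 0 min replicate 1 the counts of called genes were 423, 995 and 1081, mostly rises. Without replicate 1 or 2 at 15 min they were 10 and 29, without replicate 1 or 2 at 30 min 4 and 5, and without replicate 2 at 60 min 27.

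In promoter-proximal windows, where polymerase pauses, 9 genes were called at 15 min (1 up, 8 down), 30 at 30 min and 59 at 60 min (all down) of 11491 with edgeR. RPL38 changed by −1.40 ± 0.20, −1.81 ± 0.21 and −2.0 ± 0.21 and RPL36 by −1.20, −1.57 and −1.79 at the 3 times, and RPL24 reached −2.28 ± 0.25 at 60 min (adjusted p = 0.000198). RPL7L1, RPL9, RPL6 and CCT7 also fell at 15 min, as did NACA (−1.09 ± 0.19, adjusted p = 0.0419). The readthrough locus RPS10-NUDT3, whose reads are shared with RPS10, fell by 1.32 (adjusted p = 0.0159), and MAF1, a repressor of RNA polymerase III, rose (1.01 ± 0.18, adjusted p = 0.0381). Ribosomal protein genes had medians of −0.31, −0.38 and −0.72 with 4, 16 and 25 called, and adjusted p = 0.121, 0.0777 and 0.0259 with an estimated correlation. WDR5-bound genes had medians of −0.36, −0.40 and −0.51 with 8, 24 and 46 called, and adjusted p = 0.0305, 0.017 and 0.00615 with an estimated correlation. Of the falls, 8 of 8, 24 of 30 and 46 of 59 were at bound genes. The count at 15 min was 0 without 0 min replicate 2, 15 min replicate 1 or 15 min replicate 2. Without 1 library the count at 30 min was 10 (0 min replicate 2) or 0 (30 min replicate 1 or 2), and at 60 min 39 (0 min replicate 2), 464 (60 min replicate 1) or 38 (60 min replicate 2).

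The ratio of promoter-proximal to gene-body counts changed at few genes, 5 at 15 min (4 up, 1 down), 6 at 30 min (1 up, 5 down) and 24 at 60 min (3 up, 21 down) of 17208 with edgeR. CSNK1E (1.41 ± 0.27, adjusted p = 0.00483), the polymerase subunit POLR2K (1.45 ± 0.32, adjusted p = 0.0316) and the cytokine receptor IL6ST (1.12 ± 0.26, adjusted p = 0.042) rose at 60 min, and RPL24 (−1.30) and HDAC8 (−1.69) fell. At 15 min the RNA helicase gene DDX39B (1.14 ± 0.23), CYB561D2 (1.48 ± 0.29) and MAF1 (1.17 ± 0.24) rose and the haem-degrading enzyme gene HMOX1 fell (−1.28 ± 0.23, adjusted p = 0.0167). Ribosomal protein genes had median changes of 0.25, −0.10 and −0.30, and adjusted p = 0.266, 0.594 and 0.25 with an estimated correlation. DESeq2 called 0, 2 and 1 genes. At 15 min edgeR called 0 without 0 min replicate 2 or 15 min replicate 1, 2 without 0 min replicate 1 and 16 without 15 min replicate 2. At 30 min it called 32 without 0 min replicate 1 and 0 without any of the other 3 libraries. At 60 min it called 49 and 3 without 0 min replicates 1 and 2, and 440 and 7 without 60 min replicates 1 and 2.

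After 72 h of C6 in MV4:11, ribosomal protein, cell cycle, histone and mitochondrial ribosomal protein genes lay lower as groups, and no single gene passed the threshold with every library. These group shifts were called with the preset correlation and lost with an estimated one (adjusted p = 0.237, 0.15, 0.15 and 0.237 in that order). Of 74 ribosomal protein genes, 72 had a lower mean after C6 than under DMSO, with a median log2 fold change of −0.61 and 0 called, also when adjusted over the list alone. RPL6 was at −0.99 ± 0.31, CCT7 at −1.13 ± 0.36, CSNK1E at −0.89 ± 0.26 and the growth factor IGF1 at 1.28 ± 0.40. None of them was called (lowest edgeR adjusted p of all genes, 0.459). WDR5 itself (ENSG00000196363.5, 9:137000487-137025093) was at 5.68 ± 0.17 against 5.86 ± 0.05 log2 CPM (SD, n = 5; log2 fold change −0.17 ± 0.10, edgeR adjusted p = 0.633). CDKN1A (0.13 ± 0.50), MDM2 (0.29 ± 0.10), MYC (−0.06 ± 0.14), and the MLL-fusion targets HOXA9 (−0.09 ± 0.13) and MEIS1 (−0.18 ± 0.16) were not called.

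With all 5 replicates edgeR called 0 of 19823 genes, against 1868 at an unadjusted p below 0.05 (580 up, 1288 down) and 4 called by DESeq2. The camera test with the preset correlation placed ribosomal proteins (adjusted p = 6.65e-27), cell cycle genes (median −0.53, 35 down when adjusted over the list alone, adjusted p = 2.45e-38), histones (−0.50, 12 down when adjusted over the list alone, adjusted p = 4.35e-13) below other genes. With an estimated correlation their adjusted p = 0.237, 0.15 and 0.15, so none of the calls held. Mitochondrial ribosomal proteins (−0.27, adjusted p = 6.58e-17), translation factors (−0.24, adjusted p = 2.05e-09) and ribosome biogenesis genes (−0.21, adjusted p = 7.51e-09) also lay below, with adjusted p = 0.237 for each with an estimated correlation. Oxidative phosphorylation genes (−0.21, adjusted p = 1.08e-06) and noncoding snoRNA host genes (−0.21, adjusted p = 0.00309) lay below and p53 targets (0.10, adjusted p = 0.00154) above other genes, with adjusted p = 0.416 for each with an estimated correlation. Genes bound by WDR5 had a median of −0.32, with 33 down and 1 up when adjusted over the list alone (camera adjusted p = 1.98e-25, and adjusted p = 0.15 with an estimated correlation).

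The shift followed WDR5 binding within the ribosomal protein genes. Bound ones had a median log2 fold change of −0.80 and the others −0.16. Per library, the mean log2 CPM of bound minus other ribosomal protein genes was 0.136 ± 0.383 for C6 and 0.893 ± 0.113 for DMSO (SD, n = 5). The difference was −0.757 (95% interval −1.06 to −0.341; exact two-sided permutation p = 0.0238, with 0.00794 the smallest possible). Within batches the difference was −0.971 in replicates 1 to 3 (exact permutation p = 0.1, the smallest possible) and −0.436 in replicates 4 and 5 (exact permutation p = 1, with 0.333 the smallest possible). The library labelled C6 replicate 5 lay at 0.81, among the DMSO libraries, and the library labelled C6nc replicate 4 at −0.13, among those labelled C6, and these 2 are called doubted below.

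Other groupings of the MV4:11 libraries were tried after seeing the data. Against DMSO, C6 gave 811 called genes in replicates 1 to 3 (144 up, 667 down of 21823; edgeR; 2100 with 144 up under library size alone, 539 with 166 up under RLE factors, 1934 with 553 up by DESeq2), 0 in replicates 4 and 5 (565 at an unadjusted p below 0.05) and 0 with a batch term and all libraries. Without the libraries labelled C6nc replicate 4 and C6 replicate 5, 262 were called. Without the library labelled C6 replicate 5 alone 185 were called (18 up, 167 down). The genes described next come from replicates 1 to 3, a choice made after the data were seen, and the result with every library remains 0. In this fit the count was 1 without C6 replicate 2, 343 without C6 replicate 3, and 20, 19 and 172 without DMSO replicates 1, 2 and 3. MT-RNR2 took 26.6%, 40.3% and 34.4% of the counts in its C6 libraries and 26.1% ± 1.14 under DMSO (n = 3, 25.1% to 27.3%).

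In replicates 1 to 3, the falls were led by SLFN11 (ENSG00000172716.12, 17:33677324-33700720), which sensitises cells to DNA damage, at −2.13 ± 0.17 (SE; edgeR adjusted p = 0.00206), and CCT7 (ENSG00000135624.11, 2:73460548-73480149), at −1.80 ± 0.15 (adjusted p = 0.00206). With them fell RPL36 (ENSG00000130255.8, 19:5674958-5691887; −1.78 ± 0.22) and RPL6 (ENSG00000089009.11, 12:112842994-112856642; −1.57 ± 0.17, adjusted p = 0.00527). The rises were led by the growth factor IGF1 (ENSG00000017427.11, 12:102789645-102874423; 1.93 ± 0.28, adjusted p = 0.0101). Of 73 ribosomal protein genes 38 fell (42 when adjusted over the list alone), with a median of −0.92, camera adjusted p = 5.4e-50, and adjusted p = 0.198 with an estimated correlation. Of 39 bound ones 36 fell (median −1.29) and of 31 others 0 (median −0.29). Their reads can be shared with many processed pseudogenes, so single values are uncertain. WDR5-bound genes had 57 down and 1 up of 145 (median −0.53, camera adjusted p = 3.55e-45, and adjusted p = 0.137 with an estimated correlation). Of 561 falls with a known start site 57 were bound (Fisher's exact p = 3.07e-43, over genes not independent). Without C6 replicate 2, edgeR called 1 gene in this fit.

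Cell cycle genes fell at 33 of 45 (41 when adjusted over the list alone; median −0.81, camera adjusted p = 3.36e-51, and adjusted p = 0.0537 with an estimated correlation). They included the mitotic kinase CDK1 (−1.06 ± 0.14), the replication factor CDC45 (−0.85 ± 0.12) and cyclin B2, CCNB2 (−0.81 ± 0.11). Histone genes fell at 8 of 19 (15 when adjusted over the list alone; median −0.74, adjusted p = 0.206 with an estimated correlation), including HIST1H1B (−1.05 ± 0.17) and HIST1H3B (−1.02 ± 0.20), whose copies are near-identical. Mitochondrial ribosomal proteins fell at 12 of 72 (50 when adjusted over the list alone; median −0.47, adjusted p = 0.24 with an estimated correlation). Targets of p53 rose at 4 of 40 (6 when adjusted over the list alone; median 0.23, adjusted p = 0.267 with an estimated correlation). These were PLK3 (1.01 ± 0.12), the apoptosis gene BBC3 (0.88 ± 0.14), BTG2 (0.77 ± 0.15) and CDKN1A (0.65 ± 0.13, edgeR adjusted p = 0.028). In replicates 4 and 5, where SLFN11 was lower and CDKN1A higher under DMSO already, SLFN11 was at −1.0 ± 0.77, CDKN1A at −0.16 ± 0.15, IGF1 at 0.48 ± 0.16, CCT7 at −0.58 ± 0.42 and RPL6 at −0.41 ± 0.40 (edgeR adjusted p = 0.999 for each). These values average C6 replicate 4 with the doubted library labelled C6 replicate 5, where CCT7 was at 6.88 and 8.25 log2 CPM and RPL6 at 8.50 and 9.92. MT-RNR2 took 33.8% ± 6.86 of counts in the C6 libraries behind these groups.

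In the same replicates 1 to 3, ribosome biogenesis genes had a median of −0.39 with 2 of 34 down (16 when adjusted over the list alone). Translation factors had a median of −0.43 with 2 of 35 down, noncoding snoRNA host genes −0.39 with 1 of 13 down, and cholesterol synthesis genes −0.33 with 2 of 20 down. With an estimated correlation these 4 lists had adjusted p = 0.198, 0.267, 0.385 and 0.267. Oxidative phosphorylation genes had a median of −0.38 with 0 of 31 called (13 down when adjusted over the list alone; adjusted p = 0.299 with an estimated correlation). Myeloid markers had 2 up, ITGAX (1.31 ± 0.19) and ITGAM (0.85 ± 0.18), and 3 down, with MNDA at −1.37 ± 0.17, and a median of 0.07 (camera adjusted p = 0.536). Interferon-stimulated genes (0.49) and lymphoid and stromal markers (0.51) had 0 called, with adjusted p = 0.267 and 0.497 with an estimated correlation. MLL-fusion targets (−0.14, 0 of 18), erythroid markers (0.35, 1 up and 1 down of 17) and WDR5 partners (−0.07, 1 down of 24) had camera adjusted p = 0.25, 0.411 and 0.131. The ATF4 response (0.02) and housekeeping controls (−0.17) had camera adjusted p = 0.31 and 0.25. The BCL2 family had a median of −0.04 and a mean of 0.09 (adjusted p = 0.498). WDR5 (−0.29 ± 0.13), MDM2 (0.25 ± 0.15) and MEIS1 (−0.34 ± 0.25) were not called.

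In K562, C6 called 48 genes with every library, 44 of them lower and 13 of these ribosomal proteins, and erythroid genes rose as a group. RPS4X (ENSG00000198034.6, X:71475529-71497150), a protein of the small ribosomal subunit, fell from 9.63 ± 0.06 to 8.70 ± 0.13 log2 CPM (SD, n = 5), a log2 fold change of −0.92 ± 0.07 (SE; edgeR adjusted p = 3.51e-05). CSNK1E (ENSG00000213923.6, 22:38686697-38794527) fell from 5.93 ± 0.11 to 4.83 ± 0.17 (−1.09 ± 0.10, adjusted p = 0.000115). RPL27 (−0.92 ± 0.12), RPL7 (−0.90 ± 0.15), RPL32 (−0.80 ± 0.10), the initiation factor gene EIF4G3 (1:21132963-21503377; −0.84 ± 0.09) and CDKN1A (−0.55 ± 0.08, adjusted p = 0.00809) also fell. UROS (ENSG00000188690.8, 10:127477146-127511817), an enzyme of haem synthesis, rose from 5.00 ± 0.13 to 5.56 ± 0.12 (0.56 ± 0.10, adjusted p = 0.0196).

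With edgeR, 48 of 21800 genes were called (4 up, 44 down), 86 with library size alone (22 up, 64 down) and 194 by DESeq2 (43 up, 151 down). Of 73 ribosomal protein genes 13 fell (35 when adjusted over the list alone; median −0.44, camera adjusted p = 9.68e-54, and adjusted p = 0.107 with an estimated correlation), 12 of 42 bound ones (median −0.61) and 0 of 28 others (median 0.11). Of 22 falls with a known start site 16 were bound (Fisher's exact p = 2.23e-20, over genes not independent). The 427 bound genes as a set had a median of −0.01, which was 0.02 with library size alone (16 down; 39 down and 2 up when adjusted over the list alone; adjusted p = 0.77 with an estimated correlation). Erythroid and megakaryocyte markers had a median of 0.43, with 1 of 24 up and, when adjusted over the list alone, 8 up and 1 down (camera adjusted p = 3.11e-23, and adjusted p = 0.000633 with an estimated correlation). Bound minus other ribosomal protein genes were at −0.425 ± 0.0320 after C6 and 0.266 ± 0.0488 under DMSO (SD, n = 5). The difference was −0.691 (95% interval −0.756 to −0.631; exact permutation p = 0.00794, the smallest possible), and within batches it was −0.691 in replicates 1 to 3 and −0.692 in replicates 4 and 5. WDR5 (0.03 ± 0.19), MDM2 (−0.07 ± 0.10), MYC (0.01 ± 0.09) and MEIS1 (−0.05 ± 0.19) were not called. The count was 0 in replicates 1 to 3 (410 at an unadjusted p below 0.05), 702 in replicates 4 and 5 and 197 with a batch term, alternatives added after seeing the data. Without 1 library it was 11 (C6 replicate 1), 19 (C6 replicate 3), 16 (C6 replicate 4), 30 (C6 replicate 5), 31 (DMSO replicate 2), 15 (DMSO replicate 4) or 13 (DMSO replicate 5).

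Replicates 4 and 5 alone, which differed least between replicates, named further genes (245 up, 457 down of 19902; edgeR). Of 24 erythroid markers 14 rose and 1 fell (median 0.33, adjusted p = 0.197 with an estimated correlation). Among them were the embryonic globin gene HBZ (0.89 ± 0.12), HBA2 (0.81 ± 0.11), HBG1 (0.51 ± 0.06) and HEMGN (0.54 ± 0.06). HBA2 and HBG1 share reads with their near-identical copies HBA1 and HBG2. Ribosomal proteins fell at 41 of 73 (median −0.52, adjusted p = 0.197 with an estimated correlation), 39 of 42 bound ones. RPL7 was at −0.97 ± 0.05 (adjusted p = 2.6e-09) and CSNK1E at −1.02 ± 0.06 (adjusted p = 1.49e-08). Translation factors had 5 down and 1 up, with EEF2 at −0.57 ± 0.04. The snoRNA host genes SNHG15 (−0.95 ± 0.07), SNHG17 (−0.46) and GAS5 (−0.37) fell. Myeloid markers had 5 down of 17 (median −0.24, adjusted p = 0.197 with an estimated correlation). Targets of p53 had 4 down and 1 up of 34, with CDKN1A at −0.65 ± 0.10. Without DMSO replicate 4 or 5 the count of 702 was 371 or 385.

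Most other lists in K562 stayed near 0 with all 5 replicates. Mitochondrial ribosomal proteins (median 0.05), cell cycle genes (0.04), MLL-fusion targets (0.04) and the ATF4 response (0.00) had camera adjusted p = 0.206, 0.314, 0.699 and 0.699. Interferon-stimulated genes (0.03), the BCL2 family (−0.02), cholesterol synthesis genes (−0.01) and housekeeping controls (−0.01) had camera adjusted p = 0.96, 0.354, 0.365 and 0.699, and the last 3 medians were above 0 with library size alone. Oxidative phosphorylation genes (0.08, adjusted p = 0.0423), ribosome biogenesis genes (0.07, adjusted p = 0.0151) and p53 targets (−0.02, adjusted p = 0.0174) gave adjusted p = 0.903, 0.903 and 0.817 with an estimated correlation. The p53 median was 0.0035 with library size alone. For several lists the median and the test differed in sign. Myeloid markers had a median of 0.10 and a test towards lower values (adjusted p = 0.0368, and adjusted p = 0.77 with an estimated correlation). Translation factors (median 0.05, mean −0.01), noncoding snoRNA host genes (0.12) and lymphoid and stromal markers (0.39) also had tests towards lower values, with camera adjusted p = 0.258, 0.648 and 0.107. Histones (median 0.03, mean −0.14) and WDR5 partners (0.03, mean −0.01) had camera adjusted p = 0.365 and 0.694.

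C6nc, the inactive control compound, called 0 genes against DMSO in either line (edgeR; 50 at an unadjusted p below 0.05 in MV4:11 and 78 in K562; 0 with DESeq2 in both). In K562 the bound minus other ribosomal protein genes differed from DMSO by 0.0127 after C6nc (95% interval −0.0652 to 0.0906; exact permutation p = 0.690), and in MV4:11 by −0.203 (−0.658 to 0.156; exact permutation p = 0.429). Without the doubted library labelled C6nc replicate 4 the MV4:11 difference was 0.0026 (exact permutation p = 0.992). Ribosomal protein genes had medians of −0.04 in K562 (0.0029 with library size alone) and −0.12 in MV4:11, with adjusted p = 0.684 and 0.972 with an estimated correlation. In batches, 1 gene was called in replicates 4 and 5 of MV4:11, LAIR1, an inhibitory receptor (−3.56 ± 0.33, adjusted p = 0.0222), where 1 of the 2 libraries is the doubted one labelled C6nc replicate 4. In replicates 4 and 5 of K562 2 were called, RN7SL396P (1.32 ± 0.11) and the ubiquitin gene UBB (0.51 ± 0.07). These 3 genes were named after their values were seen.

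Compared directly at the same dose and time, C6 and C6nc differed in K562 at 36 genes (5 up, 31 down after C6; edgeR). RPS4X (−0.84, adjusted p = 0.00012), CSNK1E (−1.07), RPL27 (−0.81) and CDKN1A (−0.56, adjusted p = 0.00909) were lower after C6. HBZ (1.05 ± 0.18), the alpha-globin chaperone AHSP (1.02 ± 0.17), SLIT2 (0.70 ± 0.12), UROS (0.58 ± 0.10) and the oxysterol-binding protein OSBP2 (0.47 ± 0.08) were higher. Ribosomal protein genes had 10 down (33 when adjusted over the list alone; median −0.42, adjusted p = 0.263 with an estimated correlation). Erythroid markers had 2 up (9 when adjusted over the list alone; median 0.46, adjusted p = 0.000228 with an estimated correlation). Bound minus other ribosomal protein genes differed by −0.704 (95% interval −0.768 to −0.646; exact permutation p = 0.00794, the smallest possible). The count was 0 in replicates 1 to 3 (266 at an unadjusted p below 0.05) and 526 in replicates 4 and 5. Without 1 library it was 6 (C6 replicate 1), 5 (C6 replicate 3), 6 (C6 replicate 4), 7 (C6 replicate 5), 9 (C6nc replicate 2), 13 (C6nc replicate 3), 8 (C6nc replicate 4) or 6 (C6nc replicate 5). DESeq2 called 136.

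In MV4:11, C6 and C6nc differed at 0 genes with every library (1621 at an unadjusted p below 0.05; 0 with DESeq2) and at 41 without the library labelled C6 replicate 5. Ribosomal protein genes had a median difference of −0.44 (adjusted p = 0.243 with an estimated correlation). Cell cycle genes were at −0.48 (35 down when adjusted over the list alone; adjusted p = 0.0826 with an estimated correlation) and lymphoid and stromal markers 1.32 (adjusted p = 0.361 with an estimated correlation). Bound minus other ribosomal protein genes differed by −0.554 (95% interval −1.02 to 0.0802; exact permutation p = 0.119), an interval that holds 0 and also the K562 value, so the compounds are not shown to act alike. It was −0.759 without the library labelled C6nc replicate 4 (exact permutation p = 0.0238) and −0.722 without the one labelled C6 replicate 5 (exact permutation p = 0.0397). In replicates 1 to 3 the difference was −0.931 (exact permutation p = 0.1, the smallest possible) and in replicates 4 and 5 it was 0.0131. In replicates 1 to 3, 1198 genes differed (193 up, 1005 down; edgeR), among them CCT7 (−1.87 ± 0.15) and CSNK1E (−1.38 ± 0.11). That count was 37 without C6 replicate 2, 784 without C6 replicate 3, and 304, 326 and 130 without C6nc replicates 1, 2 and 3. In replicates 4 and 5 LAIR1 alone differed (3.55 ± 0.33, adjusted p = 0.0235), each group holding 1 of the 2 doubted libraries.

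**Figure D2:**
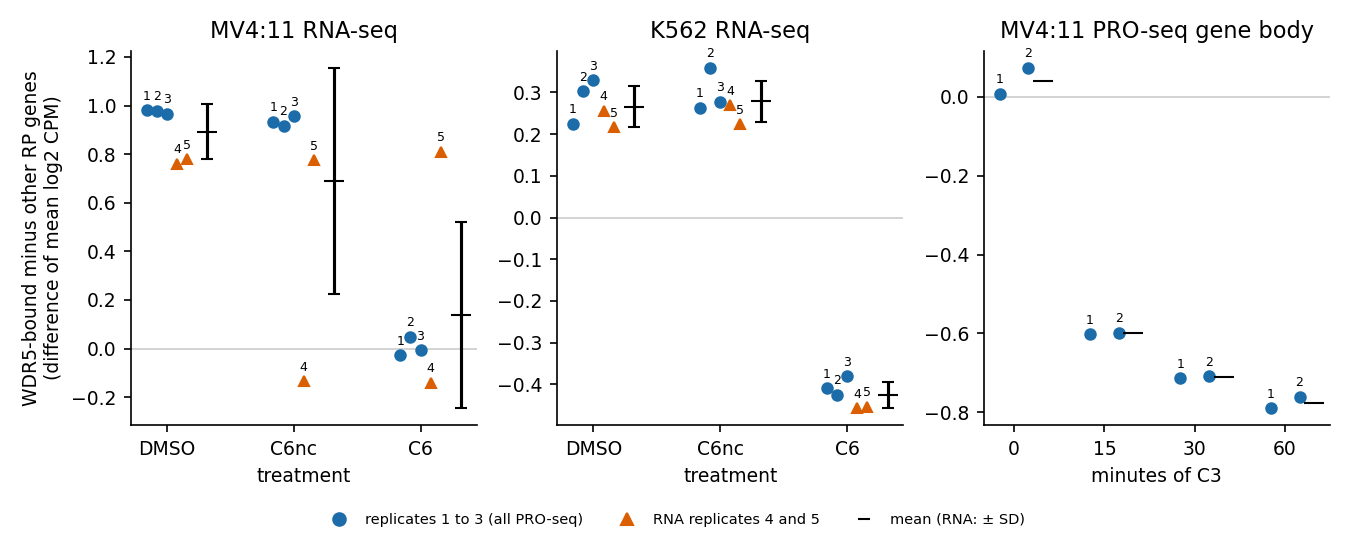
Difference of mean log2 CPM between WDR5-bound and other ribosomal protein genes (vertical axis) in each library of MV4:11 RNA-seq, K562 RNA-seq and MV4:11 PRO-seq gene bodies, with circles for RNA-seq replicates 1 to 3 and for PRO-seq, triangles for RNA-seq replicates 4 and 5, numbers for the replicate and dashes for means (with SD in RNA-seq). C6 lay at −0.425 ± 0.0320 in K562 against 0.266 ± 0.0488 under DMSO, while in MV4:11 the libraries labelled C6 replicate 5 (0.81) and C6nc replicate 4 (−0.13) lay apart from their groups.

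Whether C6 acts differently in the 2 lines was tested as an interaction, and no single gene passed. With edgeR 0 of 25890 genes were called (939 at an unadjusted p below 0.05; 13 with DESeq2), the lowest adjusted p being 0.143. Cell cycle genes had the largest difference among lists that passed camera with the preset correlation, a median of −0.51 for MV4:11 minus K562 (adjusted p = 6.06e-36, and adjusted p = 0.0803 with an estimated correlation). Ribosomal protein genes differed by −0.17 (adjusted p = 2.26e-07, and adjusted p = 0.694 with an estimated correlation). Falls in MV4:11 replicates 1 to 3 and in K562 replicates 4 and 5, which share no library, had 102 genes in common against 16.9 for independent lists, and rises had 2 against 1.57. Across all genes these 2 sets of fold changes, which come from different batches, had r = 0.00797 and rho = −0.00836. The C6 effects in the 2 lines had r = 0.418 and rho = 0.237 with every library and r = 0.352 and rho = 0.276 with replicates 1 to 3 of both. Within a line, the 2 batches had r = 0.172 in MV4:11 and r = 0.165 in K562. Genes are not independent replicates in any of these values. In replicates 1 to 3 alone the interaction called 0 genes (1243 at an unadjusted p below 0.05).

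After Nutlin in MV4:11, 21 of 40 p53 targets rose and 44 of 45 cell cycle genes fell. As sets, p53 targets lost their call with an estimated correlation (adjusted p = 0.0969) and cell cycle genes kept it (adjusted p = 0.0458). CDKN1A (ENSG00000124762.9, 6:36644305-36655116) rose by 1.04 ± 0.08 (SE, n = 3; edgeR adjusted p = 0.000149), MDM2 (ENSG00000135679.17, 12:69201956-69239214), a ubiquitin ligase gene, by 0.71 ± 0.06, BBC3 by 1.12 ± 0.11 and BTG2 by 0.79 ± 0.07. The largest rises included those of the glutathione-degrading enzyme gene CHAC1 (ENSG00000128965.7, 15:41245160-41248710; 3.29 ± 0.48, adjusted p = 0.00158), the cystine transporter gene SLC7A11 (2.99 ± 0.41) and the mTOR inhibitor gene DDIT4 (2.67 ± 0.39). The largest falls included SLC38A5 (−1.0 ± 0.10), the replication factor GINS1 (−0.97 ± 0.08), CDKN3 (−0.95 ± 0.07) and CDC20 (−0.86 ± 0.07). WDR5 fell by 0.36 (adjusted p = 0.00138), and MYC (−0.08) and HOXA9 (−0.07) were not called. In total 5446 of 24375 genes were called (2028 up, 3418 down), and without the DMSO library of column 3 the count was 3362. MT-RNR2 took 19.5%, 21.3% and 20.8% of counts in the Nutlin libraries and 17.3%, 15.3% and 16.7% in their DMSO libraries.

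By list, 21 of 40 p53 targets rose and 1 fell (24 and 3 when adjusted over the list alone; median 0.32, camera adjusted p = 2.04e-11, and adjusted p = 0.0969 with an estimated correlation). Cell cycle genes fell at 44 of 45 (median −0.63, adjusted p = 0.0458 with an estimated correlation). Histones fell at 19 of 21 and 1 rose (−0.52; adjusted p = 0.0969 with an estimated correlation). Ribosome biogenesis genes fell at 31 of 35 (−0.37; adjusted p = 0.0969 with an estimated correlation). Mitochondrial ribosomal proteins fell at 61 of 75 (−0.34; adjusted p = 0.229 with an estimated correlation). The ATF4 response rose at 16 of 24 (19 when adjusted over the list alone; median 1.39; adjusted p = 0.299 with an estimated correlation). Cytosolic ribosomal proteins fell at 26 of 79 (median −0.15; adjusted p = 0.474 with an estimated correlation). They fell at 15 of 39 WDR5-bound ones (median −0.17) and 9 of 36 others (−0.14). WDR5-bound genes had 60 down and 2 up of 141 (−0.17, adjusted p = 0.158 with an estimated correlation).

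The other lists after Nutlin were as follows, each with its adjusted p with an estimated correlation where camera with the preset value had called it. Translation factors fell at 18 of 36 (median −0.20; adjusted p = 0.229) and oxidative phosphorylation genes at 23 of 31 (−0.29; adjusted p = 0.229). Housekeeping controls fell at 8 of 12 (−0.29; adjusted p = 0.155), cholesterol synthesis genes at 7 of 22 (−0.26; adjusted p = 0.512) and WDR5 partners at 8 of 26 (−0.15; adjusted p = 0.299). Myeloid markers had 11 up and 3 down of 31 (0.32; adjusted p = 0.0969). Interferon-stimulated genes had 5 up of 25 (0.43; adjusted p = 0.229) and lymphoid and stromal markers 4 up of 12 (0.95; adjusted p = 0.229). Noncoding snoRNA host genes (median −0.05), MLL-fusion targets (−0.06, mean 0.10), erythroid markers (0.40) and the BCL2 family (−0.07, mean 0.12) had camera adjusted p = 0.115, 0.357, 0.145 and 0.485.

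C6 and Nutlin, each against its own DMSO libraries in MV4:11, gave no called gene in the joined fit (0 of 27610 with edgeR, 300 at an unadjusted p below 0.05, 0 with DESeq2). In simulated data this fit called 25 of 100 genes changed 2-fold and 0 of 100 changed 1.5-fold, so it does not show that the 2 compounds act alike. As lists, ribosomal proteins were lower after C6 than after Nutlin (median difference −0.51, camera adjusted p = 2.6e-17, and adjusted p = 0.392 with an estimated correlation). So were the ATF4 response (−0.86, adjusted p = 3.59e-26, and adjusted p = 0.127 with an estimated correlation) and p53 targets (−0.21, adjusted p = 8e-07, and adjusted p = 0.345 with an estimated correlation). With C6 replicates 1 to 3 alone, 2 genes were called, the adhesion receptor gene LPHN3 (−1.34 ± 0.18, adjusted p = 0.035) and CSNK1E (−1.16 ± 0.17, adjusted p = 0.0449), named after their values were seen. CSNK1E was at −0.10 ± 0.05 after Nutlin (adjusted p = 0.202) and SLFN11 at −0.83 ± 0.14 (adjusted p = 0.00276). Across genes the effects of C6 (all libraries) and Nutlin had r = 0.735 and rho = 0.741, over genes that are not independent replicates. Of the falls in replicates 1 to 3 after C6, 529 of 653 tested in both also fell after Nutlin, against 108 for independent lists. Of the rises 118 of 142 were shared, against 12.7.

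**Figure D3:**
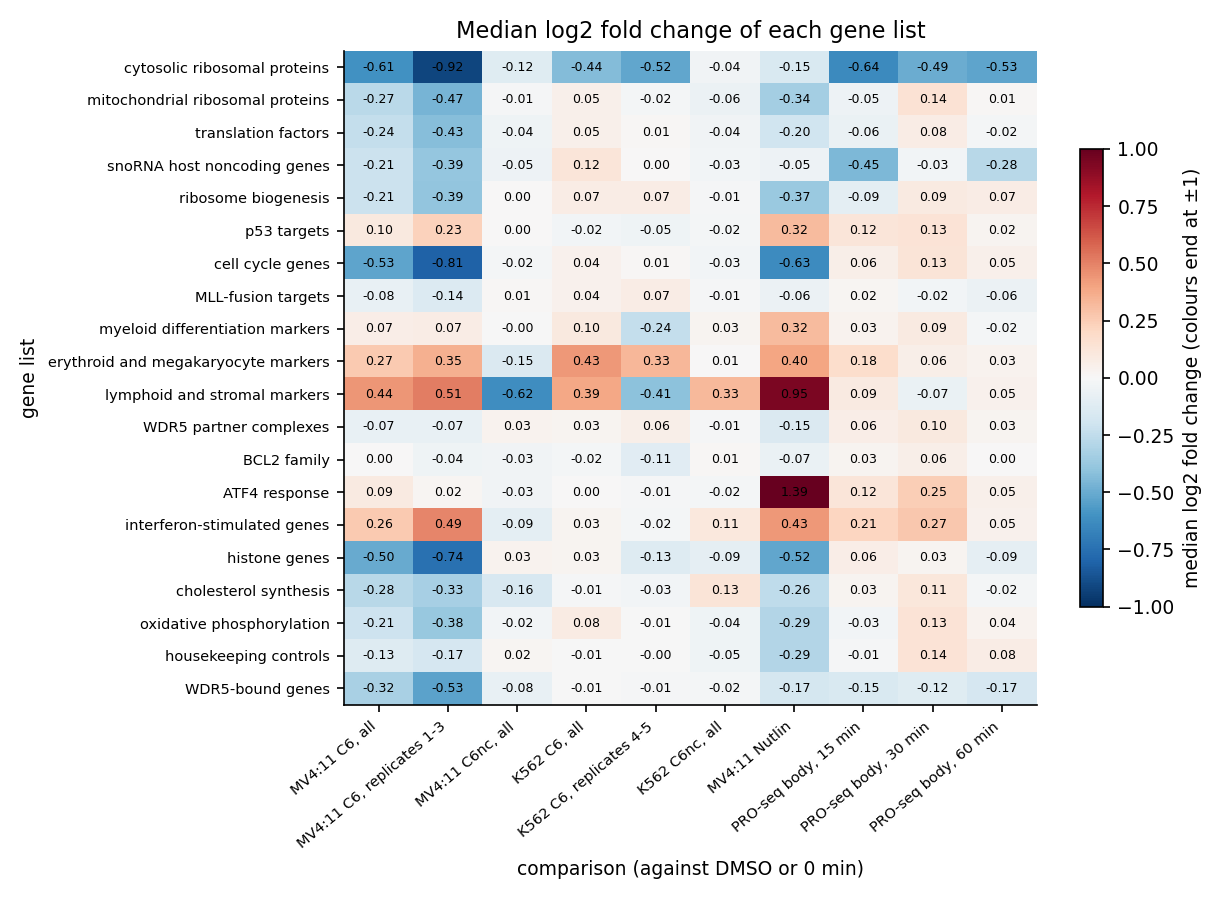
Heat map of the median log2 fold change of the 19 fixed gene lists and the WDR5-bound genes (vertical axis) in 10 comparisons (horizontal axis), with the value printed in each cell and colours ending at 1 on either side of 0. Ribosomal protein genes ran from −0.92 (MV4:11 C6, replicates 1 to 3) to −0.04 (K562 C6nc, 0.0029 with library size alone), while cell cycle genes were at −0.63 after Nutlin and 0.04 after C6 in K562.

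Genes that changed early in PRO-seq were compared with those that changed after 72 h in other libraries and with another compound of the class. Of 41 gene bodies that fell after 15 min of C3 and were tested in both, 37 also fell in RNA after C6 in MV4:11 replicates 1 to 3, against 1.62 for independent lists, and after 60 min 36 of 41. With K562 C6 RNA, 13 falls were shared with those at 60 min, against 0.0636. The compound, the dose label and the time differ between these experiments, so the values stand side by side and are no test of either compound.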

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

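The tests of batch, of the size of the effect by batch, of the spread between libraries, of depth for the MV4:11 result (made in K562) and of splits where no gene was called were chosen only after their results were seen, as were the fits by batch and without the doubted libraries.

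Single libraries lay far from their group by Dixon's test in 5 of 87 groups of 5 libraries, where 1 in 20 gives 4.35 by chance. In MV4:11 the mean of WDR5-bound minus other ribosomal protein genes was −0.13 in the library labelled C6nc replicate 4, against 0.78 to 0.96 in the other libraries of its group. The library labelled C6 replicate 5 was at 0.81, against −0.14 to 0.05 in the others. In K562, UROS was at 4.78 log2 CPM in DMSO replicate 3 (others 5.03 to 5.08), RPL7 at 9.65 in C6nc replicate 1 (others 10.27 to 10.37) and MYC at 7.79 in C6 replicate 3 (others 8.12 to 8.25).

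The effect of C6 in MV4:11 differed from that in K562 for 10 gene sets by camera with the preset correlation. The median differences were −0.51 for cell cycle genes, −0.44 for histones, −0.26 for ribosome biogenesis, −0.25 for mitochondrial ribosomal proteins, −0.24 for oxidative phosphorylation, −0.21 for translation factors, −0.21 for noncoding snoRNA host genes, −0.17 for cytosolic ribosomal proteins, −0.10 for WDR5-bound genes and 0.12 for p53 targets, the last being −0.0085 with library size alone. With an estimated correlation 0 of the 10 differences held, the adjusted p running from 0.0803 for cell cycle genes to 0.694.

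In MV4:11, C6 called 0 genes with every library (1868 at an unadjusted p below 0.05; 4 with DESeq2) and 811 in replicates 1 to 3. A shift between batches that every group shares and library depth are argued against as the cause, since a batch term still gave 0 calls, and in K562 the deeper replicates 4 and 5 called 702 genes more than replicates 1 to 3. A mislabelled sample is a candidate explanation that stays open: over 15 genes outside the ribosomal proteins that fell in PRO-seq, the library labelled C6 replicate 5 (mean log2 CPM 7.14) lay 0.740 above the library labelled C6nc replicate 4 (6.40), with the DMSO and C6nc controls at 7.19, C6 replicate 4 at 6.43 and the same difference in K562 at −0.52. An exchange of these 2 labels may therefore account for the missing calls, 262 genes being called without both libraries (185 without C6 replicate 5 alone), but it and a C6 effect that differs between batches cannot be told apart: the shift of bound against other ribosomal protein genes differed between the batches by −0.535 (SD of libraries 0.354), and 1 of only 2 C6 libraries in replicates 4 and 5 is the doubted one. No biological explanation was tested.

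In K562, C6 called 702 genes in replicates 4 and 5 and 0 in replicates 1 to 3 (410 at an unadjusted p below 0.05). Library depth is argued against as the whole cause, since 557 genes were called (514 of them also before) after thinning replicates 4 and 5 to 23.1 M counts. A smaller effect in replicates 1 to 3 is argued against as well, since the shift of bound against other ribosomal protein genes differed between the batches by 0.00141, with an SD between libraries of 0.0442. A wider spread between libraries stays open and may account for it, the median residual variance being 0.114 in replicates 1 to 3 and 0.0122 in replicates 4 and 5, a ratio of 9.31 (2.33 in MV4:11). No biological explanation was tested.

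Other splits of the libraries were drawn for each comparison. For C6 against DMSO in K562, 1 of 100 splits, the real one, gave as many calls (48, highest other 0). For the ribosomal protein median it was 1 of 100 in K562 (size 0.437, highest other 0.404). In MV4:11 it was 4 of 100 (0.609, highest other 0.835). For C6 against C6nc in K562, 3 of 100 splits gave as many calls (36). A split with all 4 libraries of replicates 4 and 5 in 1 group called 5877 genes, which points to the batch. Within batches that comparison called 0 genes in replicates 1 to 3 and 526 in replicates 4 and 5. All these splits mix the batches, so their shares do not exclude chance. The ribosomal protein list also lost its call with an estimated correlation in both lines (adjusted p = 0.237 in MV4:11). The split with 0.835 exchanged C6 replicate 5 with DMSO replicate 3. Where the real split called 0 genes, 100 of 100 splits necessarily gave as many, so the splits decide nothing about chance: the highest others were 6745 for C6 and 4138 for C6nc against DMSO and 3614 for C6 against C6nc in MV4:11, 2156 for C6nc in K562, 12085 for the difference between the lines and 0 for C6 minus Nutlin. The first 4 of these put all 4 libraries of replicates 4 and 5 into one group, and within batches the real counts were 811, 0, 1198 and 0 in replicates 1 to 3 and 0, 1, 1 and 2 in replicates 4 and 5. With 3 libraries against 3, the 10 splits are too few for a share under 0.05. There 1 of 10 splits, the real one, was as large for Nutlin (5446, highest other 0), for C6 against DMSO in replicates 1 to 3 of MV4:11 (811, highest other 0) and for C6 against C6nc there (1198, highest other 0).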

How the results depend on the processing

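Fits by batch, with a batch term, without the 2 doubted libraries and with crossed numbers, and all alternatives of the fits of replicates 1 to 3 and of replicates 4 and 5, were chosen only after the data were seen. Over the alternatives run, no named gene that was called, no peak value and no difference of bound against other ribosomal protein genes between C6 and DMSO changed sign. Directions did change elsewhere: without 0 min replicate 1, which leaves 1 library assumed to vary like the other groups, gene-body calls became mostly rises (358 of 423 at 15 min, against 3 of 52), and several list medians changed sign with the scaling, mostly near 0, such as that of p53 targets in the difference between lines (0.12, and −0.0085 with library size alone). Counts of called genes stayed within 1.5 times in 194 cases and moved in 126, and ChIP values did so in 34 and 9. Set tests kept their side of the threshold in 1037 cases, lost it in 186 and gained it in 19, named genes in 1783, 333 and 3, and bound against other ribosomal protein genes in 85, 9 and 2. Where no cause is given, the cause was not tested. The median of all genes was shifted by −0.108 in MV4:11 C6nc against DMSO and by 0.119 for Nutlin with library size alone, by 0.113 in MV4:11 replicates 1 to 3 with RLE factors, and by 0.110 for C6 against C6nc there with TMM (0.132 with RLE, 0.162 with library size alone). What depth limits was tested only by thinning K562 replicates 4 and 5 to 23.1 M counts, which gave 557 calls, 514 of them among the 702 before. In simulated data, 2-fold changes were called at 3 of 100 genes with K562 replicates 1 to 3, 23 for ratios, 25 for C6 minus Nutlin, 31 for the difference between lines and 53 for promoter-proximal windows, limits that join depth, spread and number of libraries.

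With consensus in every replicate, a stricter set by construction, the reverse overlap of the antibodies was 80.6% (66.4% otherwise), that of the lines 90.3% (83.6%) and its reverse 19.4% (25.0%). With peaks of −log10 q of at least 5, C6 minus DMSO was −159.67 peaks per MV4:11 library (−199). Requiring 2-fold in addition, fewer genes passed by construction: 15, 4 and 16 PRO-seq gene bodies at 15, 30 and 60 min, 5 in K562 C6 against DMSO and 3 against C6nc, 44 and 32 in its replicates 4 and 5, 208 and 287 in MV4:11 replicates 1 to 3, and 917 for Nutlin. DESeq2 called 56 gene bodies at 30 min, 23 and 52 promoter-proximal windows at 15 and 30 min, 0, 2 and 1 ratios, 13 genes in the difference between lines, 194 and 136 in K562 C6 against DMSO and C6nc, 4 in MV4:11 C6 against DMSO, and 1934 and 2433 in its replicates 1 to 3. With library size alone the counts were 4 and 19 promoter-proximal windows at 15 and 30 min, 0, 1 and 9 ratios, 1 gene in the difference between lines, 86 (22 up, 64 down) and 63 in K562, and 2100 (144 up, 1956 down) in MV4:11 replicates 1 to 3 against DMSO. There the share of rises was 6.86%, against 17.8% with TMM and 30.8% with RLE factors, which called 539 (166 up, 373 down), and in K562 it was 25.6% against 8.33%. Without the low-count filter 33, 53 and 101 promoter-proximal windows passed, 4 and 1 genes in K562 against DMSO and C6nc, and 142 and 273 in MV4:11 replicates 1 to 3. With only the 2 groups compared, K562 C6 against C6nc gave 14.

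Replicates 4 and 5 alone gave 702 and 526 genes in K562 C6 against DMSO and C6nc and 2 for C6nc against DMSO, 1 each in MV4:11 C6nc against DMSO and C6 against C6nc, and 2 in the difference between lines. Replicates 1 to 3 alone gave 0 and 0 in K562 (edgeR; 410 and 266 at an unadjusted p below 0.05), 811 and 1198 in MV4:11 and 2 for C6 minus Nutlin. Bound against other ribosomal protein genes stood at −0.692 and −0.691 in K562 and −0.436 and −0.971 in MV4:11 in these 2 parts, where so few libraries cannot reach 0.05. A batch term gave 197 and 121 in K562. Without the libraries labelled C6nc replicate 4 and C6 replicate 5, 262 and 184 genes were called in MV4:11 against DMSO and C6nc, 2 in the difference between lines and 6 for C6 minus Nutlin.

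Same-numbered departures correlated at 0.027 to 0.84 in MV4:11 and −0.087 to 0.89 in K562, so no pairing was assumed. Yet 10 of 15 libraries in each line correlated best with their own number, a structure the main fits leave in the spread. In PRO-seq 0 of 8 did so by gene bodies and 2 of 8 by promoter-proximal windows. With a replicate block, 1228 and 925 genes were called in K562 replicates 4 and 5, 365 (117 up, 248 down) and 307 with all K562 libraries, 1681 and 3532 in MV4:11 replicates 1 to 3 against DMSO and C6nc, 8 in the difference between lines and 0 promoter-proximal windows at 15 min, and within-number differences of bound against other ribosomal protein genes were −0.691 in K562 and −0.757 in MV4:11 (exact permutation p = 0.125, the smallest for 5 pairs being 0.0625). With crossed numbers, a replicate block called 23 promoter-proximal windows at 15 min. No paired analysis was run for Nutlin or C6 minus Nutlin, although both Nutlin arms hold columns 2, 3 and 5.

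With an estimated correlation, the ribosomal protein list had adjusted p = 0.248 and 0.0675 in PRO-seq gene bodies at 30 and 60 min, 0.237 in MV4:11, 0.198 in its replicates 1 to 3, 0.107 in K562, 0.694 for the difference between lines, 0.474 for Nutlin and 0.392 for C6 minus Nutlin. WDR5-bound genes had 0.248, 0.0675, 0.150, 0.137, 0.770, 0.694, 0.158 and 0.474 in the same order, and p53 targets 0.416 in MV4:11, 0.267 in its replicates 1 to 3, 0.0969 for Nutlin and 0.345 for C6 minus Nutlin. Under the other settings run for these sets, library size alone, the block and a distance of 5 kb, their adjusted p stayed below 0.05, the highest being 0.00351 for p53 targets in MV4:11.

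Leaving out 1 library gave 10 (15 min replicate 1) to 423 (0 min replicate 1) gene bodies at 15 min, 4 (30 min replicate 1) to 995 (0 min replicate 1) at 30 min and 27 (60 min replicate 2) to 1081 (0 min replicate 1) at 60 min. Promoter-proximal windows ran from 0 to 6, from 0 to 31 and from 38 to 464, and ratios from 0 to 16, from 0 to 32 and from 3 to 440, the libraries being named with those results. K562 gave 11 (C6 replicate 1) to 54 (DMSO replicate 1) against DMSO and 5 (C6 replicate 3) to 29 (C6nc replicate 1) against C6nc, and its replicates 4 and 5 gave 371 (DMSO replicate 4) to 774 (C6 replicate 5) and 245 (C6nc replicate 4) to 703 (C6 replicate 4). MV4:11 gave 0 to 185 and 0 to 41, both highest without C6 replicate 5, and its replicates 1 to 3 gave 1 (C6 replicate 2) to 841 (C6 replicate 1) and 37 (C6 replicate 2) to 1141 (C6 replicate 1). Nutlin ran from 3362 (DMSO column 3) to 7097 (Nutlin column 5). C6nc against DMSO in both lines, the difference between lines and C6 minus Nutlin stayed at 0. For peaks a replicate number was left out of every group at once, which also changed the consensus regions. The overlap of the antibodies ran from 58.6% to 77.5% and its reverse from 70.7% to 80.6%, regions found after C6 from 18.9% to 39.1% and after C6nc from 78.7% to 94.6%, and C6 minus DMSO peaks from −241.5 to −174.5. The overlap of the lines was 88.4% and its reverse 21.5% without replicate 3, and no replicate of 2 could be left out of K562 peaks. Bound against other ribosomal protein genes ran from −0.70 to −0.68 in K562 and from −0.93 to −0.69 in MV4:11. Of the called genes named, those losing their call without 1 library were 28 of 29 in MV4:11 replicates 1 to 3, 4 of 9 in K562, 8 of 32 in its replicates 4 and 5, 4 of 65 for Nutlin, 3 of 11, 4 of 8 and 0 of 8 in gene bodies, 9 of 9, 8 of 8 and 0 of 8 in promoter-proximal windows and 5 of 5, 6 of 6 and 10 of 11 in ratios.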

Other observations

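The test of reads shared with pseudogenes was chosen only after its result was seen, as were the genes of the next paragraph for a look across experiments.

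Outside the ribosomal protein list, CSNK1E had a WDR5 region at its promoter in both lines and was lower in each experiment with a WIN-site compound. Its gene body fell by 0.85 at 15 min, 1.14 at 30 min and 1.29 at 60 min of C3 in MV4:11, and its RNA changed by −1.09 ± 0.10 (SE) after C6 in K562 (edgeR adjusted p = 0.000115) and by −1.28 ± 0.11 in MV4:11 replicates 1 to 3 (adjusted p = 0.00208). With every MV4:11 library it was at −0.89 ± 0.26 and not called (adjusted p = 0.459). After C6nc it was at −0.02 ± 0.10 in K562 and 0.10 ± 0.11 in MV4:11 replicates 1 to 3, and after Nutlin at −0.10 ± 0.05, none of them called. EIF4G3, bound in both lines, fell in K562 (−0.84 ± 0.09) and was at −0.62 ± 0.18 in MV4:11 replicates 1 to 3 (adjusted p = 0.0948). PRRC2B, without a region at its start site, was at −0.81 ± 0.21 in K562 (adjusted p = 0.2) and fell by 0.66 in its replicates 4 and 5.

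Interferon-stimulated genes had medians above 0 in gene bodies early after C3, a shift called with the preset correlation and lost with an estimated one. Of 27 measured, 27 had a positive log2 fold change at 15 min (median 0.21, 2 up when adjusted over the list alone) and 26 at 30 min (median 0.27, 3 up), with none called over all genes. The camera adjusted p was 1.19e-09 and 2.87e-09, and with an estimated correlation the adjusted p = 0.236 and 0.303. At 60 min the median was 0.05 and 18 of 27 were positive (camera adjusted p = 0.545).

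Pseudogenes of ribosomal proteins moved with their parent genes after C6. In MV4:11 replicates 1 to 3, the 90 pseudogenes whose parent is WDR5-bound had a median log2 fold change of −0.76 with 22 called, and the 53 others −0.13 with 0 called, a difference of −0.626. The same difference was −0.480 in K562 and −0.557 in its replicates 4 and 5. Reads shared between a parent and its copies may account for these falls, so calls of such pseudogenes stand for their parents as much as for themselves. No biological explanation was tested.

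A hypothesis written down before its test was that polymerases already on a gene take longer to clear a long gene, so that long gene bodies fall late. Among the 52 gene bodies that fell at 60 min of C3, Spearman's rho between gene length and the 60 min minus 15 min log2 fold change was −0.613 (permutation p = 1e-05, the smallest the permutations drawn can give), across genes that are not independent replicates. The 43 that had also fallen at 15 min had a median length of 6.22 kb, and the 9 that had not 70.1 kb, among them PRRC2B, which went from −0.04 to −0.85. Uncalled genes showed rho = −0.275 over 17937 genes and the 23 called genes outside the ribosomal proteins −0.70. Clearance of long genes and a trend of all genes with length thus cannot be told apart, and both stay open. Only the change from 15 to 60 min was compared with length.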
